A study of Homo sapiens with 8 samples.

How the data were processed

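The data are bulk RNA sequencing libraries of human NK cells expanded with 2 feeder systems. Per the labels, mononuclear cells from buffy coats were cultured with feeder cells irradiated with 10000 rad, IL-2 at 200 U/ml and IL-15 at 5 ng/ml, and NK cells were then sorted as CD3-negative and CD56-positive to a purity above 98%. Total RNA was sequenced from cells of the 221-mIL21 and K562-mIL21 systems on day 7 and day 14, with 2 libraries per group, 4 groups and 8 libraries. The values are raw read counts per gene, as the authors deposited them in 1 matrix. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.6.1d. The counting tool, its handling of strand and its gene annotation are not given in the sources used here. All 8 columns were used, and 0 columns were left out.

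The matrix had 25221 genes, of which 25116 were matched to RefSeq genes of GRCh38.p14 and 105 were not (0.0430 to 0.0551% of counts per library). It held 6346 genes without a read in any library. It held no transcripts of the mitochondrial genome, so the list of mitochondrial transcripts was not analysed here and 37 of the 38 gene lists were tested. Each list needed at least 3 tested members.

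Libraries held 18735698 to 19627796 counts, with 15758 to 16585 genes read at least once. The most abundant gene, ACTB, took 1.45 to 2.41% of counts. At these depths 3 counts, the upper limit that 0 reads allow, correspond to 0.153 to 0.160 CPM per library before TMM scaling. In comparisons of 2 groups, ratios against a group with at most 3 reads in each library carry an exact binomial 95% counting interval. It covers counting error only, and at 0 reads a lower bound is given instead. Folds averaged over both days carry no such interval. Replicates of 221-mIL21 differed by more than counting error (chi-squared per degree of freedom 5.25 on day 7 and 5.30 on day 14). Those of K562-mIL21 also did, by a smaller margin (1.51 and 1.97).

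Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 13355, and libraries were scaled by TMM (factors 0.944 to 1.08). All 8 libraries were fitted with 1 mean per group, leaving 4 residual degrees of freedom, and the common biological coefficient of variation was 0.0420. Contrasts were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. A standard error given for a median over genes is taken across those genes as if independent, and does not measure spread between libraries. The 6 comparisons were 221-mIL21 against K562-mIL21 on day 7, on day 14 and averaged over both days, day 14 against day 7 within each system, and the interaction of system and day. Group means and SDs are of TMM-scaled CPM over 2 libraries. CPM values in the marker check are before TMM scaling, except the EBI3 fold. So are the list sums and the T cell gene values among the results flagged for a closer look.

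Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 37 lists of a comparison. Each list test was repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Calls per member were made over all genes and adjusted over the list alone. The lists cover cytotoxic effectors, activating and inhibitory receptors, CD56bright and CD56dim genes, cytokines, chemokines, homing receptors, cytokine receptors with STAT genes, the TNF family, transcription factors and early response genes. Metabolic lists cover glycolysis, the tricarboxylic acid cycle, respiratory complexes, cholesterol synthesis, fatty acids, serine and one-carbon enzymes, nucleotide synthesis, the pentose phosphate pathway and amino acid transport with ATF4 targets. Growth and stress lists cover MYC and ribosome biogenesis, S phase, mitosis, cell survival, interferon-stimulated genes, MHC class II processing, the unfolded protein response, heat shock, hypoxia and ribosomal proteins. Marker lists cover T cells, innate lymphoid cells, the B lineage of the 221 feeder, the erythroid lineage of K562, myeloid cells and platelets. The expected overlap of calls is the product of the numbers called in each comparison and direction, divided by the number of genes tested.

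The comparisons, gene lists, threshold and alternatives were chosen before the data were examined. So was the rule for naming genes: for each comparison of 2 groups the 6 largest rises and 6 largest falls among genes that passed, with groups that did not overlap and at least 5 CPM in the higher group. The rule adds up to 3 members per gene list, the sort and feeder markers, 3 rises and 3 falls of the average over days and the 6 interactions with the smallest p. Y-linked genes, XIST, HLA, KIR, immunoglobulin and T cell receptor segment genes and unnamed loci were left out. The rule gave 481 entries for 284 genes. The text names fewer, mainly those of the lists that passed, and this narrowing was chosen after the number was known. Some genes that the rule names are not reported here. CD79A, PAX5, PTGDS, CD3G, CD5 and CD28 fall outside it and were chosen after their values were seen.

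Named genes were placed on GRCh38, and for 292 of them the exons shared with other genes on either strand and the 50-base words shared with other transcripts were computed from GENCODE v29. At least 20% was shared in 33 genes, and those named are given as uncertain. The chain was tested on counts simulated from the mean CPM, the dispersion per gene and the library sizes of these data. In 200 genes changed per comparison it recovered 68.7 to 82.1% of 1.5-fold, 83.6 to 97.0% of 2-fold and 93.9 to 100% of 4-fold changes. It called 0.0304 to 0.0912% of unchanged genes. In the real comparisons 49.5 to 74.4% of genes passed, and the adjusted threshold depends on that share. Neither the recovery nor the false call rates therefore need carry over to the real comparisons.

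Alternatives were RLE size factors, library size as the only scaling, no low-count filter, at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a replicate block, only the groups compared, each library left out in turn and a model of 2 groups that ignores day. A block with the replicate numbers of 1 group exchanged, a test against a 1.5-fold change and the effect correlation under each alternative were added after seeing the data. Corrections for GC content and gene length, marker sums and library splits are described with their results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.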

Results

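RNA was sequenced from human natural killer (NK) cells that had been expanded from blood mononuclear cells with irradiated feeder cells carrying membrane-bound interleukin 21 (IL-21). One feeder was 221-mIL21, made from a B-lymphoblastoid line that lacks HLA class I. The other was K562-mIL21, made from K562, a leukaemia line of erythroid character. Cells were sorted as CD3-negative and CD56-positive after 7 or 14 days, which gave 4 groups of 2 libraries. The 8 libraries held 18735698 to 19627796 counts, and 13355 of the 25221 genes had enough reads to be tested. The question was how NK cells from the 2 systems differed on each day and how they changed between the days. The labels do not say whether the replicates were separate cultures or donors, so every p-value measures only the spread between these libraries, which may be technical. Expression is given as mean TMM-scaled CPM ± SD (n = 2), and a gene "passed" at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test over all tested genes. Gene lists were tested with camera at a preset correlation of 0.01 between genes. No list in any comparison passed when this correlation was estimated, so the list calls rest on the preset form of the test. The size of the correlation alone does not explain this. Homing receptors on day 7 had an estimated correlation of 0.0095, under the preset value, and adjusted p still went from 3.3e-07 to 0.114.

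The first principal component of log2 CPM held 73.5% of the variance. It ordered the libraries from 221-mIL21 day 7 (weights 0.561 and 0.556) through K562-mIL21 day 7 (0.0458 and 0.0472) to 221-mIL21 day 14 (-0.258 and -0.269) and K562-mIL21 day 14 (-0.341 and -0.341). The second component, with 11.5%, separated K562-mIL21 day 7 from the other groups. Replicates correlated across genes at a Pearson r of 0.996 to 0.998, where genes are not independent replicates.

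**Figure D1:**
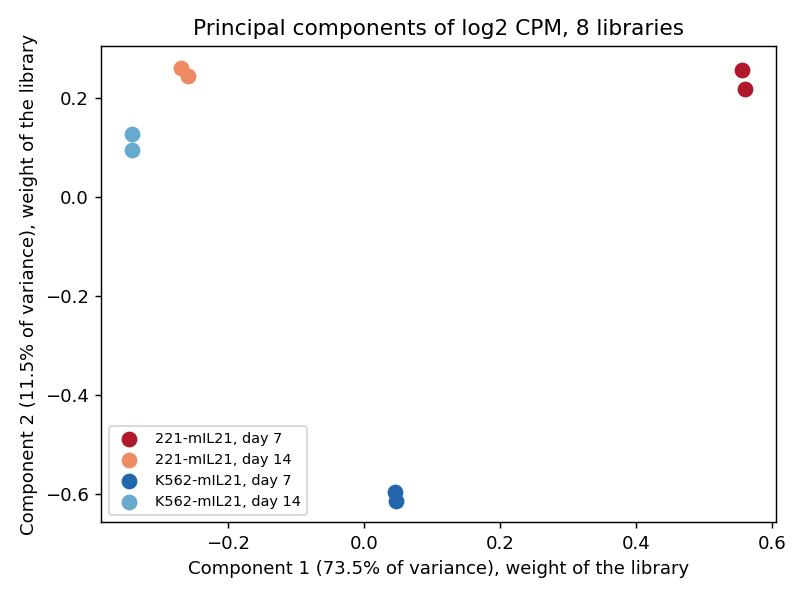
Weights of the 8 libraries on the first and second principal components of log2 CPM (73.5% and 11.5% of the variance), 1 point per library, coloured by group. The 221-mIL21 day 7 libraries lie at weights of 0.561 and 0.556 on the first component, apart from the other 6.

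The sort markers and the markers of the feeder lines were read in every library. NCAM1, which encodes CD56 (GRCh38 chromosome 11, 112961420 to 113278436), had 315 to 617 CPM before TMM scaling. CD3D, a T cell receptor subunit, had 0.316 to 4.53 CPM. CD3E, another subunit of the same complex (chromosome 11, 118304730 to 118316173), was far more abundant, with means of 66.1 and 393 CPM in the 221-mIL21 libraries of day 7 and day 14 and 167 and 496 CPM in those of K562-mIL21. The B cell gene MS4A1 had 0 to 12 reads per library. The erythroid gene HBG1 and IL21 itself had 0 reads in all 8 libraries, which allows up to 0.153 to 0.160 CPM per library (3 counts). HBG1 shares 30.9% of its 50-base words with another gene, so its value is uncertain. These floors and the intervals given elsewhere cover counting error only. On day 7, EBI3 (2.6 CPM with 221-mIL21, 0 reads with K562-mIL21) and CD70 (11.6 and 1.91 CPM) differed, while MS4A1 (0.344 and 0.464 CPM), CD79A (0.872 and 0.929 CPM) and PAX5 (1.06 and 1.03 CPM) lay close together. In TMM-scaled values EBI3 was at least 15.2-fold higher with 221-mIL21 than the 3-count floor per library.

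The day 7 comparison asked which genes differed between the systems early in the expansion. NK cells from 221-mIL21 had less RNA for the receptors and granule proteins of mature CD56dim NK cells and more for interferon-stimulated genes. CX3CR1, a chemokine receptor of CD56dim NK cells (GRCh38 chromosome 3, 39263494 to 39292966), had 31.0 ± 0.389 CPM with 221-mIL21 and 495 ± 9.78 CPM with K562-mIL21 (log2 fold change -3.99, SE 0.07, adjusted p = 3.7e-23). NCR3, which encodes the activating receptor NKp30 (chromosome 6, 31588895 to 31593006), had 53.9 ± 0.0776 and 328 ± 4.50 CPM (log2 fold change -2.60, SE 0.06, adjusted p = 1.7e-20). IFI44L, a gene induced by type I interferon (chromosome 1, 78620448 to 78646145), was 15.3-fold higher, at 588 ± 57.6 against 38.5 ± 0.639 CPM (log2 fold change 3.93, SE 0.08, adjusted p = 4.3e-22). Of the 13355 genes, 8324 passed, 4194 higher and 4130 lower with 221-mIL21, and 2035 of them differed at least 2-fold (1218 higher, 817 lower). Of the genes that passed, 50.4% were higher. With library size as the only scaling this share was 65.5%, and the median tested gene lay at 0.15 instead of near 0, so the changes given here are relative to TMM scaling.

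Of the 20 CD56dim genes, 2 were higher, 17 lower and 1 did not pass (median log2 fold change -2.06, adjusted p = 1.0e-07, adjusted p = 0.115 with an estimated correlation), and the median was -1.83 with PTGDS, at 0 reads in both 221-mIL21 libraries, set to its bound. The CD56bright list also lay lower without passing (median -0.32, adjusted p = 0.0596, adjusted p = 0.321 with an estimated correlation), and it passed with library size as the only scaling (0.0298), without a low-count filter (0.0194) and without K562-mIL21 day 7 replicate 2 (0.0396). FGFBP2, a secreted protein of cytotoxic lymphocytes, was 12.7-fold lower, and CXCR1, an IL-8 receptor, 24.8-fold lower. Of 22 activating receptor genes, 0 were higher, 19 lower and 3 did not pass (median -0.96, adjusted p = 1.0e-07, adjusted p = 0.114 with an estimated correlation). FCGR3A, the IgG receptor CD16, was 4.68-fold lower, but 30.1% of its 50-base words are shared with FCGR3B, so its value is uncertain. Of 20 cytotoxic effector genes, 2 were higher, 17 lower and 1 did not pass (median -0.82, adjusted p = 2.9e-06, adjusted p = 0.252 with an estimated correlation): the granule protease GZMA had 343 ± 16.4 against 1157 ± 24.0 CPM and the granule membrane protein NKG7 568 ± 27.1 against 1985 ± 40.8 CPM. The death ligand TNFSF10 (TRAIL), an interferon-inducible member of that list, went the other way, 1.63-fold higher. Homing receptor genes were lower too (of 26, 4 were higher, 22 lower and 0 did not pass, median -1.06, adjusted p = 3.3e-07, adjusted p = 0.114 with an estimated correlation). In contrast, the lymph node receptor CCR7 was 12.4-fold higher (287 ± 20.5 against 23.1 ± 0.0962 CPM). Among 17 inhibitory receptor genes 4 were higher, 13 lower and 0 did not pass (median -0.83, adjusted p = 0.00132, adjusted p = 0.252 with an estimated correlation), with LAIR1 5.72-fold lower and TIGIT 2.23-fold higher. Of 13 cytokine genes 2 were higher, 9 lower and 2 did not pass (median -0.81, adjusted p = 0.00440, adjusted p = 0.252 with an estimated correlation). Lymphotoxin beta, LTB, was 7.34-fold lower. Of 27 early response genes 5 were higher, 14 lower and 8 did not pass (median -0.58, adjusted p = 0.00650, adjusted p = 0.322 with an estimated correlation). The immediate early factor EGR1 was 5.43-fold lower, and the stress factor ATF3 was 4.90-fold higher.

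Of 35 interferon-stimulated genes, 30 were higher, 2 lower and 3 did not pass (median 1.09, adjusted p = 4.8e-10, adjusted p = 0.115 with an estimated correlation). The antiviral GTPase MX2 was 6.73-fold higher, while GBP1, a GTPase induced mainly by interferon gamma, was 1.47-fold lower. The interferon-induced chemokine CXCL10 had 2 reads over both K562-mIL21 day 7 libraries, a ratio of 134.7 with a 95% counting interval of 37.0 to 1118. MHC class II genes were higher (of 12, 10 were higher, 0 lower and 2 did not pass, median 0.86, adjusted p = 1.4e-04, adjusted p = 0.252 with an estimated correlation), with the master regulator CIITA 1.89-fold and the invariant chain CD74 1.74-fold higher.

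Several biosynthetic lists were also higher with 221-mIL21 on day 7, while nucleotide synthesis (median 0.20, adjusted p = 0.104, adjusted p = 0.703 with an estimated correlation), cholesterol synthesis (median 0.12) and pentose phosphate (0.22, adjusted p = 0.371, adjusted p = 0.703 with an estimated correlation) did not pass. Nucleotide synthesis passed without 221-mIL21 day 7 replicate 2 (adjusted p = 0.0461). MYC, which drives growth genes (chromosome 8, 127735434 to 127742951), had 274 ± 6.97 against 72.8 ± 1.39 CPM (log2 fold change 1.91, SE 0.06, adjusted p = 5.3e-19), and the MYC and ribosome biogenesis list moved with it (of 32, 19 were higher, 0 lower and 13 did not pass, median 0.24, adjusted p = 5.4e-04, adjusted p = 0.342 with an estimated correlation). Of 49 ribosomal protein genes 45 were higher, 0 lower and 4 did not pass (median 0.34, adjusted p = 2.6e-07, adjusted p = 0.571 with an estimated correlation). RPL5 was 1.59-fold higher. Serine synthesis and one-carbon genes were higher (of 15, 10 were higher, 1 lower and 4 did not pass, median 0.62, adjusted p = 5.1e-04, adjusted p = 0.266 with an estimated correlation). The serine enzymes PHGDH and PSAT1 (GRCh38 chromosome 9, 78297125 to 78330093) were 5.38-fold and 5.08-fold higher. Of 20 amino acid transport genes and targets of the stress factor ATF4, 17 were higher, 2 lower and 1 did not pass (median 0.63, adjusted p = 5.6e-06, adjusted p = 0.178 with an estimated correlation). VLDLR, a lipoprotein receptor, was 16.0-fold higher. Of 25 fatty acid genes 17 were higher, 3 lower and 5 did not pass (median 0.34, adjusted p = 0.00299, adjusted p = 0.305 with an estimated correlation). ACSL1, which activates fatty acids, was 3.58-fold higher. Of 15 hypoxia genes 11 were higher, 2 lower and 2 did not pass (median 0.67, adjusted p = 0.0226, adjusted p = 0.252 with an estimated correlation). The growth factor VEGFA was 6.90-fold higher, and NDRG1 was 3.58-fold lower. Unfolded protein response genes were lower (of 20, 1 was higher, 15 lower and 4 did not pass, median -0.48, adjusted p = 6.1e-04, adjusted p = 0.252 with an estimated correlation), with the chaperone HSPA5 1.88-fold lower. The tricarboxylic acid cycle list (median 0.20, adjusted p = 0.0380, adjusted p = 0.635 with an estimated correlation) did not pass without 221-mIL21 day 7 replicate 1 (adjusted p = 0.145), K562-mIL21 day 7 replicate 1 (0.0943) or either K562-mIL21 day 14 library (0.0564 and 0.0561), or with the crossed block (0.0510).

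Marker lists of other cells were small. The myeloid list (7 members tested, 6 were higher, 1 lower and 0 did not pass, median 1.66, adjusted p = 0.0371, adjusted p = 0.322 with an estimated correlation) included AIF1, 22.96 ± 3.35 against 7.62 ± 0.220 CPM. It did not pass without 221-mIL21 day 7 replicate 1 (adjusted p = 0.0576) or with library size as the only scaling (0.0864). Nor did it pass without a low-count filter (median 0.22, adjusted p = 0.237) or with a CPM of at least 1 in 4 libraries (0.187). Lists that did not pass on day 7 were B lineage (median 0.80, adjusted p = 0.104, adjusted p = 0.342 with an estimated correlation), erythroid (0.18, adjusted p = 0.943, adjusted p = 0.952 with an estimated correlation), platelet (0.14, adjusted p = 0.513, adjusted p = 0.703 with an estimated correlation), T cell (-1.25, adjusted p = 0.268, adjusted p = 0.405 with an estimated correlation) and innate lymphoid (0.41, adjusted p = 0.754, adjusted p = 0.825 with an estimated correlation). The B lineage list passed without a low-count filter (median 1.83, adjusted p = 0.00695), without 221-mIL21 day 7 replicate 2 (0.0312) and without K562-mIL21 day 7 replicate 2 (0.0396). The chemokine list (1.18, adjusted p = 0.379, adjusted p = 0.703 with an estimated correlation) and the mitosis list (-0.02, adjusted p = 0.379, adjusted p = 0.819 with an estimated correlation) did not pass either. Adjusted over the list alone, these counts were the same except in the CD56dim list (3 higher, 17 lower), the MYC and ribosome biogenesis list (18 higher, 0 lower) and the ribosomal protein list (46 higher, 0 lower). Median, mean and test differed in sign for the cytokine receptor and STAT list (median -0.06, mean 0.07, test down), the TNF family list (median -0.17, mean 0.11, test up) and the cholesterol synthesis list (median 0.12, mean -0.02, test up).

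Under the naming rule CXCL10 was furthest above K562-mIL21 on day 7, followed by ENPP2 (autotaxin, 107-fold higher, 35.1 ± 1.01 against 0.321 ± 0.00129 CPM), FAM95C and ATP12A, a proton pump subunit (66.5-fold higher). GSDME, a pore-forming gasdermin, had 3 reads in the K562-mIL21 libraries and a ratio of 68.4 (95% counting interval 23.1 to 334). FAM95C and ANKRD18A are uncertain because they share 43.7% and 31.7% of their words with other genes. Furthest below K562-mIL21 were HOXB5 (4 reads with 221-mIL21, ratio 59.3, interval 22.8 to 219), FAM131C (43.7-fold), GEM (32.1-fold), NPTX1 (30.0-fold), CXCR1 and TKTL1 (18.7-fold).

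The day 14 comparison asked which differences between the systems were present at the end of the expansion. Biosynthetic and lipid genes were higher with 221-mIL21, and the CD56dim, activating receptor and interferon-stimulated lists were slightly lower. SCD, the desaturase that makes monounsaturated fatty acids (GRCh38 chromosome 10, 100347233 to 100364826), had 988 ± 21.9 CPM with 221-mIL21 and 229.6 ± 0.666 CPM with K562-mIL21 (log2 fold change 2.10, SE 0.06, adjusted p = 7.5e-19). KIT, the stem cell factor receptor of immature NK and innate lymphoid cells (chromosome 4, 54657957 to 54740715), had 1.70 ± 0.386 and 26.8 ± 0.956 CPM (log2 fold change -3.97, SE 0.15, adjusted p = 4.3e-16). CD6, a T and NK cell co-receptor (chromosome 11, 60971680 to 61020377), had 0.979 ± 0.327 and 11.9 ± 0.0558 CPM (log2 fold change -3.60, SE 0.21, adjusted p = 1.6e-12). TNFRSF8, the receptor CD30, was 4.77-fold higher with 221-mIL21 (28.7 ± 2.16 against 5.99 ± 0.0431 CPM). Of the 13355 genes 6606 passed, 3520 higher and 3086 lower, and 593 differed at least 2-fold (251 higher, 342 lower). Of the genes that passed, 53.3% were higher, and 38.0% with library size as the only scaling.

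Amino acid transport genes were higher on day 14 (of 20, 16 were higher, 0 lower and 4 did not pass, median 0.79, adjusted p = 3.1e-08, adjusted p = 0.139 with an estimated correlation), among them the leucine transporter SLC7A5 (2.82-fold) and the glutathione-degrading enzyme CHAC1 (4.49-fold). Of 25 cholesterol synthesis genes 19 were higher, 1 lower and 5 did not pass (median 0.48, adjusted p = 1.6e-07, adjusted p = 0.139 with an estimated correlation). DHCR7, an enzyme of the last steps, was 2.24-fold higher. Of 25 fatty acid genes 14 were higher, 2 lower and 9 did not pass (median 0.44, adjusted p = 6.4e-05, adjusted p = 0.232 with an estimated correlation). The desaturase FADS2 was 3.11-fold higher. Of 24 glycolysis genes 19 were higher, 1 lower and 4 did not pass (median 0.45, adjusted p = 5.1e-06, adjusted p = 0.304 with an estimated correlation). GAPDH was 1.84-fold higher. Of 8 pentose phosphate genes 6 were higher, 1 lower and 1 did not pass (median 0.43, adjusted p = 0.00821, adjusted p = 0.340 with an estimated correlation). The transketolase TKT was 1.95-fold higher. Of 15 serine and one-carbon genes 12 were higher, 0 lower and 3 did not pass (median 0.44, adjusted p = 2.2e-05, adjusted p = 0.232 with an estimated correlation). MTHFD1L was 3.01-fold higher. Of 22 nucleotide synthesis genes 15 were higher, 1 lower and 6 did not pass (median 0.29, adjusted p = 3.7e-04, adjusted p = 0.341 with an estimated correlation). The guanine nucleotide enzyme IMPDH2 was 1.83-fold higher.

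Growth genes shared this direction. Of 32 genes of the MYC and ribosome biogenesis list 20 were higher, 1 lower and 11 did not pass (median 0.35, adjusted p = 5.0e-05, adjusted p = 0.304 with an estimated correlation). MYC itself had 48.3 ± 0.5003 against 24.2 ± 0.137 CPM. Of 49 ribosomal protein genes 35 were higher, 3 lower and 11 did not pass (median 0.30, adjusted p = 5.9e-07, adjusted p = 0.511 with an estimated correlation). RPL23, an exception, was 1.27-fold lower. Of 36 DNA replication and S phase genes 19 were higher, 2 lower and 15 did not pass (median 0.21, adjusted p = 3.5e-04, adjusted p = 0.341 with an estimated correlation). The helicase subunit MCM7 was 1.57-fold higher. The tricarboxylic acid cycle list was higher (of 25, 14 were higher, 2 lower and 9 did not pass, median 0.21, adjusted p = 0.00645, adjusted p = 0.498 with an estimated correlation), with MDH2 1.45-fold higher. The respiratory complex list (of 54, 24 were higher, 7 lower and 23 did not pass, median 0.13, adjusted p = 0.0293, adjusted p = 0.691 with an estimated correlation) did not pass without 221-mIL21 day 14 replicate 1 (adjusted p = 0.148), without K562-mIL21 day 14 replicate 2 (0.129) or with library size as the only scaling (0.0863). MHC class II genes were higher (of 12, 10 were higher, 1 lower and 1 did not pass, median 0.71, adjusted p = 1.5e-04, adjusted p = 0.242 with an estimated correlation), with CD74 1.54-fold higher and the protease CTSS 1.56-fold lower.

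The lists of activating receptors, CD56dim, interferon-stimulated, TNF family, cytokine, T cell and cell survival genes were lower with 221-mIL21 on day 14. Inhibitory receptors (median -0.05, adjusted p = 0.400, adjusted p = 0.635 with an estimated correlation), homing receptors (-0.05, adjusted p = 0.266, adjusted p = 0.485 with an estimated correlation) and cytokine receptors with STAT genes (-0.05, adjusted p = 0.266, adjusted p = 0.691 with an estimated correlation) did not pass. The last of these passed without 221-mIL21 day 14 replicate 2 (median -0.14, adjusted p = 0.0199). Of 22 activating receptor genes 1 was higher, 14 lower and 7 did not pass (median -0.38, adjusted p = 4.9e-04, adjusted p = 0.186 with an estimated correlation). The adhesion receptor CD2 was 1.57-fold lower, and CD160 was 2.05-fold higher. Of 20 genes of the CD56dim list 3 were higher, 12 lower and 5 did not pass (median -0.30, adjusted p = 0.00343, adjusted p = 0.258 with an estimated correlation). LAIR2, a soluble collagen receptor, was 4.92-fold lower, and the granzyme GZMH was 1.28-fold higher, while CX3CR1 itself had 921 and 951 CPM. Interferon-stimulated genes had turned round since day 7 (of 35, 4 were higher, 22 lower and 9 did not pass, median -0.26, adjusted p = 8.3e-05, adjusted p = 0.232 with an estimated correlation), with the antiviral RSAD2 2.49-fold lower and OASL 1.55-fold higher. Of 16 genes of the TNF family 1 was higher, 10 lower and 5 did not pass (median -0.56, adjusted p = 0.00154, adjusted p = 0.186 with an estimated correlation). The death receptor TNFRSF10B and the CD30 ligand TNFSF8 were 2.14-fold and 3.30-fold lower. Of 13 cytokine genes 2 were higher, 7 lower and 4 did not pass (median -0.29, adjusted p = 0.0157, adjusted p = 0.304 with an estimated correlation). LTB was 3.12-fold lower, and TNF was 1.35-fold higher. Of 12 genes of the T cell list 0 were higher, 7 lower and 5 did not pass (median -0.76, adjusted p = 0.00415, adjusted p = 0.186 with an estimated correlation). Besides CD6, the signalling protein THEMIS was 2.89-fold lower. The cell survival list mixes genes that block death, promote it or arrest the cycle (of 22, 2 were higher, 17 lower and 3 did not pass, median -0.39, adjusted p = 5.6e-05, adjusted p = 0.139 with an estimated correlation). The death inhibitor BIRC3 and the p53 antagonist MDM2 were 2.90-fold and 2.16-fold lower, and the pro-death BAK1 was 1.32-fold higher. The cytotoxic effector list did not pass on day 14 (median -0.08, adjusted p = 0.400, adjusted p = 0.730 with an estimated correlation), nor did the innate lymphoid list (median -0.19, adjusted p = 0.0523, adjusted p = 0.273 with an estimated correlation). The latter passed without a low-count filter (adjusted p = 0.0221) and with a CPM of at least 1 in 4 libraries (0.0395). It also passed without 221-mIL21 day 14 replicate 2 (0.0119), K562-mIL21 day 14 replicate 2 (0.0211) or either K562-mIL21 day 7 library (0.0463 and 0.0461). Adjusted over the list alone, these counts were the same except in the serine and one-carbon list (13 higher, 0 lower), the ribosomal protein list (37 higher, 3 lower), the S phase list (21 higher, 2 lower), the tricarboxylic acid cycle list (15 higher, 2 lower), the activating receptor list (1 higher, 15 lower) and the T cell list (0 higher, 9 lower). Median, mean and test differed in sign for the transcription factor list (median -0.08, mean 0.02, test down), the early response list (median 0.15, mean -0.03, test up), the hypoxia list (median -0.07, mean 0.14, test up) and the B lineage list (median 0.01, mean 0.04, test down).

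Beyond these lists, the costimulatory ligand CD86 (6.54-fold), the actin-bundling FSCN1 (6.10-fold) and the glycine transporter SLC6A9 (4.90-fold) were among the genes furthest above K562-mIL21. KRT5, a keratin, passed with either library left out, but its size differed: its log2 fold change of 3.34 was 2.13 without 221-mIL21 day 14 replicate 2 (adjusted p = 5.1e-05) and 3.98 without replicate 1 (adjusted p = 1.9e-10), and its SD of 6.17 was close to its mean of 7.73 CPM. NPTX1 (11.6-fold), GPR82 (7.62-fold) and SMPD3 (7.20-fold) were among those furthest below, and SLC35D2 is uncertain because it shares 32.5% of its words with another gene.

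The system effects of the 2 days were compared across the 13355 genes, which are not independent replicates. They correlated weakly (Pearson r 0.183, Spearman rho 0.0764). The r was 0.0733 without a low-count filter, 0.111 without 221-mIL21 day 14 replicate 1 and 0.107 without replicate 2. Genes higher on both days numbered 1119 (1105 expected of independent calls), genes lower on both days 1143 (954 expected), and genes with opposite directions 2204 (2058 expected). Averaged over both days, 7302 genes passed, 3560 higher and 3742 lower, of which 847 differed at least 2-fold (479 higher, 368 lower). The cytokine receptor gene CRLF2 (8.73-fold), the co-chaperone DNAJC12 (14.6-fold) and the cysteine enzyme CTH (7.37-fold) were higher in this average. The guidance receptor PLXNA4, the thrombin receptor F2RL3 and the sulfotransferase SULT1B1 were lower (10.1, 4.95 and 4.88-fold). In the average, the CD56dim list was lower (of 20, 0 were higher, 18 lower and 2 did not pass, median -1.26, adjusted p = 4.3e-10, adjusted p = 0.0878 with an estimated correlation) and the amino acid transport list higher (of 20, 16 were higher, 0 lower and 4 did not pass, median 0.81, adjusted p = 1.4e-08, adjusted p = 0.0878 with an estimated correlation). Adjusted over the list alone, these counts were the same except in the amino acid transport list (16 higher, 1 lower). Marker lists of other cells also passed in the average: T cell (median -0.80, adjusted p = 0.0170, adjusted p = 0.155 with an estimated correlation), myeloid (1.23, adjusted p = 0.0184, adjusted p = 0.245 with an estimated correlation) and B lineage (0.49, adjusted p = 0.0442, adjusted p = 0.245 with an estimated correlation). The myeloid list did not pass without a low-count filter (median -0.12, adjusted p = 0.267) or with a CPM of at least 1 in 4 libraries (0.108). The B lineage list did not pass with a CPM of at least 1 in 4 libraries (0.325), library size as the only scaling (0.0524) or the crossed block (0.0585). Nor did it pass without 221-mIL21 day 7 replicate 1 (0.0595) or 221-mIL21 day 14 replicate 2 (0.0711).

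**Figure D2:**
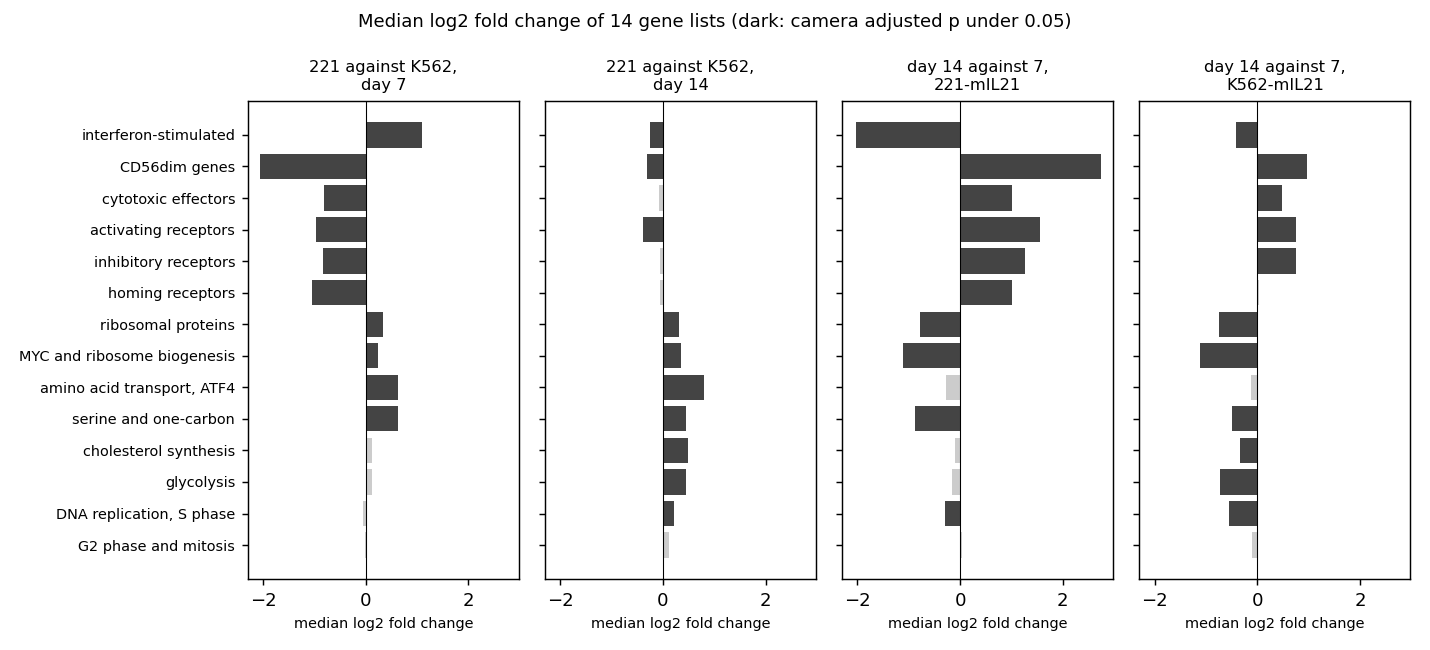
Median log2 fold change of 14 gene lists in the 4 comparisons of 2 groups, 1 bar per list; dark bars passed with camera at the preset correlation. The interferon-stimulated list lies at 1.09 on day 7, -0.26 on day 14 and -2.03 for day 14 against day 7 with 221-mIL21.

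The comparison of day 14 with day 7 in the 221-mIL21 system asked how the cells changed as expansion went on. The lists of cytotoxic, activating and inhibitory receptor and CD56dim genes rose, and those of interferon-stimulated, MYC and ribosome genes fell. CX3CR1 rose from 31.0 ± 0.389 to 921 ± 51.1 CPM (log2 fold change 4.89, SE 0.07, adjusted p = 4.2e-25). IFI44L fell 121-fold, from 588 ± 57.6 to 4.86 ± 0.828 CPM (log2 fold change -6.92, SE 0.10, adjusted p = 4.2e-25). CCR7 (GRCh38 chromosome 17, 40553769 to 40565472) fell from 287 ± 20.5 CPM to 3 reads over both day 14 libraries, a ratio of 3535 with a 95% counting interval of 1209 to 17145. TERT, the catalytic subunit of telomerase (chromosome 5, 1253167 to 1295068), had 9.88 ± 0.487 CPM on day 7 and 0 reads on day 14, at least 60.8-fold lower against the 3-count floor per library. Of the 13355 genes 9940 passed, 4854 rose and 5086 fell, and 3435 changed at least 2-fold (1632 up, 1803 down). Of the genes that passed, 48.8% were higher on day 14, and 38.9% with library size as the only scaling, which put the median tested gene at -0.18.

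Of 22 activating receptor genes 22 rose, 0 fell and 0 did not pass (median 1.55, adjusted p = 1.8e-08, adjusted p = 0.176 with an estimated correlation), among them NCR3 (11.2-fold). Of 20 cytotoxic effector genes 18 rose, 1 fell and 1 did not pass (median 1.02, adjusted p = 1.8e-06, adjusted p = 0.304 with an estimated correlation), among them the pore-forming granulysin GNLY (656 ± 18.5 to 3438 ± 165 CPM) and GZMH (8.67-fold), while TNFSF10 fell 2.78-fold. Of 20 genes of the CD56dim list 16 rose, 4 fell and 0 did not pass (median 2.75, adjusted p = 1.9e-05, adjusted p = 0.220 with an estimated correlation). FGFBP2 rose 30.6-fold and CHST2, a sulfotransferase, fell 3.12-fold. Of 26 homing receptors 20 rose, 4 fell and 2 did not pass (median 1.02, adjusted p = 2.8e-04, adjusted p = 0.189 with an estimated correlation). Of 17 inhibitory receptors 14 rose, 2 fell and 1 did not pass (median 1.26, adjusted p = 3.6e-04, adjusted p = 0.220 with an estimated correlation). CD300A rose 8.51-fold. Of 27 early response genes 20 rose, 5 fell and 2 did not pass (median 1.07, adjusted p = 5.5e-04, adjusted p = 0.318 with an estimated correlation). EGR1 rose 12.9-fold and the phosphatase DUSP4 fell 3.95-fold. Of 19 CD56bright genes 14 rose, 5 fell and 0 did not pass (median 0.83, adjusted p = 0.0220, adjusted p = 0.318 with an estimated correlation). LTB and the actin-capping CAPG rose 6.53-fold and 7.09-fold, against the fall of CCR7.

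Of 35 interferon-stimulated genes 1 rose, 32 fell and 2 did not pass (median -2.03, adjusted p = 1.3e-10, adjusted p = 0.176 with an estimated correlation), and MX1 fell 21.3-fold. CXCL10 fell at least 44.4-fold to 0 reads. Of 32 genes of the MYC and ribosome biogenesis list 0 rose, 31 fell and 1 did not pass (median -1.11, adjusted p = 5.8e-10, adjusted p = 0.279 with an estimated correlation). MYC fell 5.68-fold. All 49 ribosomal protein genes fell (median -0.78, adjusted p = 1.3e-10, adjusted p = 0.440 with an estimated correlation). Of 22 nucleotide synthesis genes 3 rose, 18 fell and 1 did not pass (median -0.78, adjusted p = 3.6e-04, adjusted p = 0.411 with an estimated correlation). The purine enzyme PAICS fell 4.11-fold. Of 15 serine and one-carbon genes 1 rose, 11 fell and 3 did not pass (median -0.87, adjusted p = 0.00245, adjusted p = 0.356 with an estimated correlation). The mitochondrial folate enzyme ALDH1L2 fell 61.6-fold. Of 14 heat shock genes 2 rose, 11 fell and 1 did not pass (median -0.82, adjusted p = 0.00337, adjusted p = 0.356 with an estimated correlation). HSP90AB1 fell 3.87-fold. Of 25 genes of the tricarboxylic acid cycle list 2 rose, 19 fell and 4 did not pass (median -0.46, adjusted p = 0.00147, adjusted p = 0.440 with an estimated correlation). DLD fell 2.31-fold and IDH2 rose 2.09-fold. Of 54 respiratory complex genes 9 rose, 32 fell and 13 did not pass (median -0.38, adjusted p = 0.00952, adjusted p = 0.670 with an estimated correlation). CYCS, cytochrome c, fell 2.69-fold. Of 36 S phase genes 8 rose, 25 fell and 3 did not pass (median -0.30, adjusted p = 0.0118, adjusted p = 0.459 with an estimated correlation). MCM6 fell 2.16-fold.

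The B lineage list (8 members tested, 1 rose, 6 fell and 1 did not pass, median -1.64, adjusted p = 0.0317, adjusted p = 0.329 with an estimated correlation) included CD40, down 7.76-fold at 3.62 CPM on day 7, and CD79B, up 2.23-fold. It did not pass with library size as the only scaling (adjusted p = 0.0683) or with a CPM of at least 1 in 4 libraries (median -0.78, adjusted p = 0.664). The myeloid list did not pass (median -3.14, adjusted p = 0.0542, adjusted p = 0.411 with an estimated correlation), although AIF1 fell 8.81-fold. The myeloid list passed with the replicate block (0.0441), with only the groups compared (0.0330), and without 221-mIL21 day 7 replicate 2 (0.0447), 221-mIL21 day 14 replicate 2 (0.0491) or either K562-mIL21 day 14 library (0.0347 and 0.0348). Among single genes, the tissue residency factor ZNF683 rose 66.6-fold, the adhesion receptor ADGRG1 54.6-fold and the raft protein MAL 60.1-fold. C19orf33 is uncertain because 54.4% of its words lie in another gene. The glycogen kinase subunit PHKA1 and the collagen COL6A3 fell to 1 read over both day 14 libraries, ratios of 541 (95% counting interval 96.8 to 21416) and 499.9 (89.3 to 19779). Adjusted over the list alone, these counts were the same except in the heat shock list (2 rose, 12 fell) and the B lineage list (1 rose, 7 fell). Median, mean and test differed in sign for the CD56bright list (median 0.83, mean -0.35, test up), the cytokine receptor and STAT list (median -0.03, mean -0.26, test up), the TNF family list (median 0.37, mean -0.05, test up), the cholesterol synthesis list (median -0.10, mean 0.19, test down), the erythroid list (median 0.01, mean -0.57, test up) and the platelet list (median -0.02, mean -0.22, test up).

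The same comparison in the K562-mIL21 system found many changes in the same direction. MYC fell from 72.8 ± 1.39 to 24.2 ± 0.137 CPM, and the MYC and ribosome biogenesis list fell (of 32, 0 rose, 31 fell and 1 did not pass, median -1.11, adjusted p = 4.1e-14, adjusted p = 0.204 with an estimated correlation). B3GAT1, which makes the CD57 epitope of terminally mature NK cells (GRCh38 chromosome 11, 134378504 to 134412242), rose from 24.5 ± 0.696 to 258 ± 4.14 CPM (log2 fold change 3.40, SE 0.08, adjusted p = 8.5e-21). KLRF1, the activating receptor NKp80 (chromosome 12, 9800052 to 9845005), rose from 19.7 ± 0.571 to 99.0 ± 2.71 CPM (log2 fold change 2.33, SE 0.08, adjusted p = 4.6e-17). The granzyme GZMB fell from 5073 ± 68.5 to 3069 ± 144 CPM. Of the 13355 genes 8190 passed, 4019 rose and 4171 fell, and 1639 changed at least 2-fold (876 up, 763 down). Of the genes that passed, 49.1% were higher on day 14, and 57.6% with library size as the only scaling.

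Activating receptors (of 22, 20 rose, 0 fell and 2 did not pass, median 0.75, adjusted p = 1.7e-08, adjusted p = 0.173 with an estimated correlation) and inhibitory receptors (of 17, 15 rose, 2 fell and 0 did not pass, median 0.75, adjusted p = 1.2e-04, adjusted p = 0.204 with an estimated correlation) rose, the latter with the checkpoint LAG3 up 2.81-fold. The CD56dim list rose (of 20, 15 rose, 2 fell and 3 did not pass, median 0.97, adjusted p = 9.4e-05, adjusted p = 0.212 with an estimated correlation), as did cytotoxic effectors (of 20, 15 rose, 1 fell and 4 did not pass, median 0.48, adjusted p = 2.7e-04, adjusted p = 0.277 with an estimated correlation), with GNLY up 1.96-fold. CD56bright genes (of 19, 13 rose, 4 fell and 2 did not pass, median 0.73, adjusted p = 0.00597, adjusted p = 0.212 with an estimated correlation) and cytokine genes (of 13, 9 rose, 1 fell and 3 did not pass, median 0.44, adjusted p = 0.00450, adjusted p = 0.212 with an estimated correlation) rose with LTB, up 2.78-fold, while IFNG fell 1.26-fold. Early response genes rose (of 27, 17 rose, 5 fell and 5 did not pass, median 0.50, adjusted p = 0.00583, adjusted p = 0.286 with an estimated correlation), with EGR2 up 4.23-fold. The cell survival list rose (of 22, 18 rose, 1 fell and 3 did not pass, median 0.50, adjusted p = 8.2e-05, adjusted p = 0.173 with an estimated correlation), led by the cycle inhibitors CDKN1A and CDKN2C (2.57-fold and 2.38-fold), which arrest the cycle and do not themselves prevent death. The TNF family list rose (of 16, 11 rose, 3 fell and 2 did not pass, median 0.82, adjusted p = 0.0165, adjusted p = 0.212 with an estimated correlation), with TNFSF8 up 6.66-fold and TNFRSF8 down 16.6-fold, and it did not pass without 221-mIL21 day 7 replicate 2 (adjusted p = 0.0501) or when only the groups compared were fitted (0.0589).

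Ribosomal protein genes fell (of 49, 1 rose, 48 fell and 0 did not pass, median -0.74, adjusted p = 4.1e-14, adjusted p = 0.286 with an estimated correlation). So did S phase genes (of 36, 1 rose, 31 fell and 4 did not pass, median -0.56, adjusted p = 1.7e-08, adjusted p = 0.212 with an estimated correlation), with GINS2 down 2.19-fold, and nucleotide synthesis (of 22, 1 rose, 20 fell and 1 did not pass, median -0.65, adjusted p = 9.6e-08, adjusted p = 0.212 with an estimated correlation), with PAICS down 3.82-fold. Of 54 respiratory complex genes 1 rose, 43 fell and 10 did not pass (median -0.36, adjusted p = 2.5e-07, adjusted p = 0.349 with an estimated correlation). ATP5F1A fell 1.90-fold. Of 25 genes of the tricarboxylic acid cycle list 1 rose, 22 fell and 2 did not pass (median -0.47, adjusted p = 1.2e-05, adjusted p = 0.280 with an estimated correlation). OGDH fell 1.95-fold. Of 24 glycolysis genes 3 rose, 19 fell and 2 did not pass (median -0.72, adjusted p = 1.6e-05, adjusted p = 0.286 with an estimated correlation). Hexokinase HK2 fell 7.98-fold and ENO2 rose 1.80-fold. Cholesterol synthesis (of 25, 2 rose, 21 fell and 2 did not pass, median -0.33, adjusted p = 8.4e-05, adjusted p = 0.204 with an estimated correlation) and fatty acid genes (of 25, 2 rose, 18 fell and 5 did not pass, median -0.40, adjusted p = 1.9e-04, adjusted p = 0.212 with an estimated correlation) fell, with SCD down 2.68-fold and ACACA, the first enzyme of fatty acid synthesis, 3.10-fold. Interferon-stimulated genes fell (of 35, 4 rose, 21 fell and 10 did not pass, median -0.42, adjusted p = 2.3e-04, adjusted p = 0.212 with an estimated correlation), with MX1 down 4.98-fold and GBP4 up 1.46-fold. Heat shock (of 14, 1 rose, 11 fell and 2 did not pass, median -0.73, adjusted p = 2.4e-04, adjusted p = 0.212 with an estimated correlation), serine and one-carbon (of 15, 1 rose, 11 fell and 3 did not pass, median -0.49, adjusted p = 4.1e-04, adjusted p = 0.228 with an estimated correlation) and pentose phosphate genes (of 8, 1 rose, 7 fell and 0 did not pass, median -0.48, adjusted p = 0.0111, adjusted p = 0.286 with an estimated correlation) fell. Unfolded protein response genes fell as well (of 20, 2 rose, 10 fell and 8 did not pass, median -0.16, adjusted p = 0.0227, adjusted p = 0.286 with an estimated correlation), with HYOU1 down 2.04-fold.

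Under the naming rule, with at least 5 CPM in the higher group, the largest falls with K562-mIL21 were CCR7 (5 reads on day 14, ratio 184.0, 95% counting interval 78.6 to 568), AK4 (22.7-fold), CD86 (21.02-fold), the proliferation factor MYB (19.6-fold), TNFRSF8 and the repressor ZBTB32 (16.6-fold). LMX1B (55.9-fold), MAL (19.9-fold), NEURL1B (12.1-fold), ADGRB2 (12.1-fold) and GLI2 (11.4-fold) rose most, and ACSL6 is uncertain because it shares 29.5% of its words with another gene. With K562-mIL21, the transcription factor list (median 0.12, adjusted p = 0.164, adjusted p = 0.561 with an estimated correlation) and the cytokine receptor and STAT list (median 0.10, adjusted p = 0.680, adjusted p = 0.847 with an estimated correlation) did not pass. The myeloid list fell without passing (median -1.86, adjusted p = 0.0512, adjusted p = 0.286 with an estimated correlation). It passed with RLE size factors (0.0457), library size as the only scaling (0.0330) and the replicate block (0.0346), and without K562-mIL21 day 7 replicate 1 (0.0307), K562-mIL21 day 14 replicate 1 (0.0334) or replicate 2 (0.0174). Adjusted over the list alone, these counts were the same except in the activating receptor list (21 rose, 0 fell), the early response list (17 rose, 6 fell), the respiratory complex list (1 rose, 45 fell), the cholesterol synthesis list (2 rose, 22 fell) and the fatty acid list (2 rose, 19 fell). Median, mean and test differed in sign for the CD56bright list (median 0.73, mean -0.17, test up), the homing receptor list (median 0.04, mean -0.24, test up), the cytokine receptor and STAT list (median 0.10, mean -0.16, test up), the innate lymphoid list (median -0.14, mean -0.01, test up) and the platelet list (median -0.05, mean -0.12, test up).

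The changes with time in both systems correlated across genes at a Pearson r of 0.649 (Spearman rho 0.573). Genes that rose in both numbered 2622 (1461 expected of independent calls), genes that fell in both 2783 (1588 expected), and genes with opposite changes 1173 (3047 expected).

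**Figure D3:**
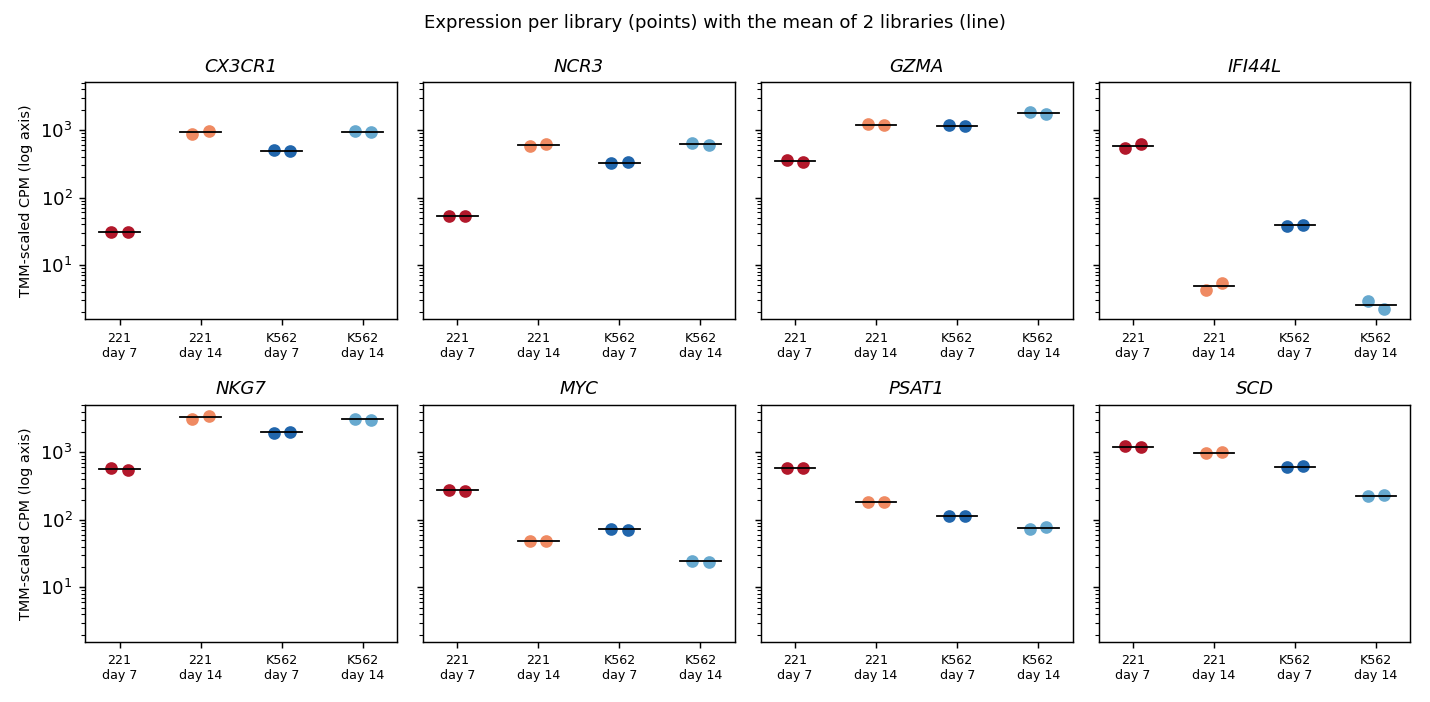
TMM-scaled CPM of 8 genes in each of the 8 libraries on a log axis, points for libraries and lines for the mean of 2 libraries per group. CX3CR1 lies at a mean of 31.0 CPM in 221-mIL21 day 7 and at 495 to 951 CPM in the other groups.

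The interaction asked which genes changed differently with time in the 2 systems, as the day 14 to day 7 change with 221-mIL21 minus that with K562-mIL21. CX3CR1 had an interaction of 3.95 (SE 0.09, adjusted p = 1.5e-20). The cell cycle factor E2F2 (3.08), the Rap1 regulator RAP1GAP2 (3.14), the quiescence factor KLF2 (3.07) and EGR1 (3.00) also had positive values. E2F2 rose with 221-mIL21 from 64.1 ± 0.610 to 346 ± 22.8 CPM and with K562-mIL21 went from 410.0 ± 1.19 to 261 ± 2.03 CPM. Of the 13355 genes 7338 passed, 3931 with a positive and 3407 with a negative interaction, and 1943 were at least 2-fold (908 positive, 1035 negative). Of the genes that passed, 53.6% were positive, and 32.6% with library size as the only scaling, which put the median tested gene at -0.24.

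In the interaction the interferon-stimulated list was negative (of 35, 2 were higher, 31 lower and 2 did not pass, median -1.60, adjusted p = 1.6e-12, adjusted p = 0.153 with an estimated correlation). The lists of cytotoxic effectors (of 20, 17 were higher, 1 lower and 2 did not pass, median 0.78, adjusted p = 2.1e-05, adjusted p = 0.388 with an estimated correlation), homing receptors (of 26, 20 were higher, 3 lower and 3 did not pass, median 0.95, adjusted p = 2.1e-05, adjusted p = 0.153 with an estimated correlation) and CD56dim genes (of 20, 15 were higher, 4 lower and 1 did not pass, median 1.80, adjusted p = 6.1e-05, adjusted p = 0.266 with an estimated correlation) were positive. So were activating receptors (of 22, 14 were higher, 2 lower and 6 did not pass, median 0.81, adjusted p = 6.0e-04, adjusted p = 0.266 with an estimated correlation), inhibitory receptors (of 17, 11 were higher, 2 lower and 4 did not pass, median 0.49, adjusted p = 0.0272, adjusted p = 0.388 with an estimated correlation) and cholesterol synthesis genes (of 25, 16 were higher, 2 lower and 7 did not pass, median 0.37, adjusted p = 0.0152, adjusted p = 0.388 with an estimated correlation), the latter not with a CPM of at least 1 in 4 libraries (adjusted p = 0.0670). The S phase (of 36, 19 were higher, 4 lower and 13 did not pass, median 0.28, adjusted p = 0.0119, adjusted p = 0.704 with an estimated correlation) and unfolded protein response lists (of 20, 12 were higher, 1 lower and 7 did not pass, median 0.32, adjusted p = 0.0181, adjusted p = 0.489 with an estimated correlation) passed with TMM scaling but not with library size as the only scaling (adjusted p = 0.116 and 0.0737). The hypoxia list (of 15, 2 were higher, 9 lower and 4 did not pass, median -0.55, adjusted p = 0.0426, adjusted p = 0.388 with an estimated correlation) did not pass with that scaling (0.0991), with a CPM of at least 1 in 4 libraries (0.0557), with the crossed block (0.0614) or without 221-mIL21 day 7 replicate 1 (0.0694) or replicate 2 (0.0588). Adjusted over the list alone, these counts were the same except in the activating receptor list (15 higher, 3 lower), the cholesterol synthesis list (16 higher, 3 lower) and the S phase list (20 higher, 4 lower). Median, mean and test differed in sign for the CD56bright list (median 0.16, mean -0.17, test up), the cytokine receptor and STAT list (median 0.13, mean -0.10, test up), the transcription factor list (median -0.07, mean 0.24, test up), the serine and one-carbon list (median 0.04, mean -0.41, test down), the heat shock list (median -0.10, mean 0.02, test down), the erythroid list (median -0.02, mean 0.11, test up) and the platelet list (median 0.01, mean -0.10, test up).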

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

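All tests of explanations in this part were chosen after the results were seen, while the test of the interaction was planned. These results stand apart because the change from day 7 to day 14 differed between the 2 systems by a test of that difference. The interaction passed for 7338 genes. All 2204 genes called in opposite directions by the system comparisons of day 7 and day 14 were among them (2058 expected of independent calls). That follows nearly by construction, because the interaction is the difference of those 2 effects. Over all tested genes 54.9% passed. Of the 284 genes named by the rule 220 passed, but the rule chose them by differences in these same libraries, some by the interaction itself. The share among named genes is therefore no separate evidence. Of the 37 gene lists tested, 10 passed at the preset correlation. Their median interactions were -1.60 for interferon-stimulated genes, 0.78 for cytotoxic effectors, 0.95 for homing receptors, 1.80 for CD56dim genes, 0.81 for activating receptors and 0.49 for inhibitory receptors. They were 0.28 for S phase genes, 0.37 for cholesterol synthesis, 0.32 for the unfolded protein response and -0.55 for hypoxia. Genes among those with the smallest p were CX3CR1 (3.95), E2F2 (3.08), RAP1GAP2 (3.14), EGR1 (3.00) and KLF2 (3.07).

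Interferon-stimulated genes were higher with 221-mIL21 on day 7, with a summed 8199.6 CPM against 3262 CPM. They fell further by day 14, to 1932 and 2668 CPM. These sums and the marker sums below are CPM before TMM scaling. The TMM factors on day 7 were 1.05 and 1.08 with 221-mIL21 and 0.967 and 0.963 with K562-mIL21, so scaling would narrow the gap. RNA of the B-lymphoblastoid feeder would bring B lineage transcripts, whose sum rose by 17.5 CPM, 0.354% of the rise of the interferon-stimulated genes. Myeloid cells that passed the sort would bring myeloid transcripts, whose sum rose by 39.3 CPM, 0.795% of it. How much marker RNA such cells carry beside interferon-stimulated RNA was not measured, so these shares do not decide either source. Day 7 medians of the marker lists were 0.80 (B lineage) and 1.66 (myeloid), and only the myeloid list passed with camera. A trend on GC content or gene length is argued against by the median interaction of -1.63 after its removal (SE across genes 0.193, camera adjusted p = 1.1e-13), against -1.60 before. A stronger interferon response of NK cells in the 221-mIL21 culture on day 7 may explain the pattern, as a hypothesis, and interferon itself was not measured. Anything else that differed between the cultures of the 2 systems, the donors included, stays open and was not tested.

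The day 7 difference between the systems ran along the change with time in the 221-mIL21 system, and less so along that in the K562-mIL21 system. The difference of K562-mIL21 from 221-mIL21 on day 7 correlated across genes with the change from day 7 to day 14 with 221-mIL21 at a Pearson r of 0.828 (covariance 0.772), where genes are not independent replicates. Both differences use the 221-mIL21 day 7 libraries, which alone gave an r of 0.483 and a covariance of 0.0157 in 20 simulations without effects. With a different day 7 library in each difference the lower r was 0.788, which argues against chance values of single libraries as the whole cause. Part of the excess may still come from the shared libraries because each split used 1 library. Replicates may be technical, and the simulations used the spread between them. A chance deviation common to both day 7 libraries would therefore not be seen by either check. After trends on GC content and length were removed r was 0.830. With the change from day 7 to day 14 with K562-mIL21 the same difference correlated at an r of 0.291 (0.314 and 0.312 with different day 7 libraries, -0.513 in simulations without effects). A faster course with K562-mIL21 may explain part of the pattern, as a hypothesis, and anything else that differed between the cultures on day 7 was not tested.

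CD3E rose from day 7 to day 14 by 327 CPM with 221-mIL21 and by 328 CPM with K562-mIL21 in cells sorted as CD3-negative. Values in this paragraph are CPM before TMM scaling. T cells that passed the sort would bring the other T cell genes, but CD3D, CD3G, CD5 and CD28 together rose by 1.68 and 3.97 CPM. That was 0.512% and 1.21% of the rise of CD3E. CD3G, CD5 and CD28 were chosen after their values were seen. CD6 and ICOS, also on the T cell list, rose with K562-mIL21, from 1.63 to 12.2 CPM and from 26.6 to 36.1 CPM. With 221-mIL21, CD6 went from 0.425 to 0.931 CPM, and ICOS fell from 66.5 to 27.4 CPM. Of the 12 tested members of that list 7 rose and 2 fell with K562-mIL21, and 5 rose and 3 fell with 221-mIL21. Reads of another gene are argued against by an overlap of 0% of the exons or 50-base words of CD3E with any other gene. A rise of CD3E transcripts within the NK cells may explain the pattern, as a hypothesis, and protein on the surface was not measured.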

How the results depend on the processing

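The crossed block, the 1.5-fold test, the correlation under each alternative and the splits of the libraries were chosen after the data were seen, and the other alternatives before the data were examined. Counts of genes stayed within 1.5 times their value in 100 of 107 combinations of comparison and alternative. The exceptions were the 1.5-fold test, which by construction calls fewer genes (2313 for the systems on day 7, 451 on day 14 and 929 averaged, 4571 and 2032 for the days with 221-mIL21 and K562-mIL21, 2214 for the interaction), and the model that ignores day, with 37 genes for the average. With 1 library left out, a group of 1 library is assumed to vary like the others, and counts ranged from 6952 to 8621 for the systems on day 7, 4887 to 6955 on day 14, 6375 to 7239 averaged, 9326 to 9921 and 6830 to 8494 for the days with 221-mIL21 and K562-mIL21, and 6410 to 7406 for the interaction. The replicate block gave 8224, 6441, 7189, 9880, 8098 and 7221 genes in the same order. Replicate deviations of different groups correlated at -0.131 to 0.139, so the numbers as labelled showed no clear pairing. With the numbers of 221-mIL21 day 14 exchanged the block gave 8522, 6851, 7538, 10081, 8409 and 7554 genes, more than the fit without a block in each comparison. Whether the libraries pair under other numbers was not settled. The correlation of the system effects of both days (0.183) was 0.0733 without a low-count filter and 0.107 to 0.199 with 1 library left out, lowest without 221-mIL21 day 14 replicate 2 (0.107) and replicate 1 (0.111), and the cause was not tested. Of the values of named genes under the alternatives, 7576 kept their side of the threshold, 93 fell below it, 7 rose past it and 0 reversed in direction. Of those of gene lists, 3421 kept their side, 152 fell below it and 125 rose past it. A reversal was counted only where the main fit or the alternative passed. Changes of direction without a pass in either are therefore among those that kept their side. An example is the TNF family list with 221-mIL21 over time (camera up, adjusted p = 0.768, fry down, adjusted p = 0.160). With fry in place of camera, 2 lists that passed with fry took the other direction, both with 221-mIL21 over time: cytokine receptors with STAT genes (median -0.032, adjusted p = 0.0464) and cholesterol synthesis (median -0.10, adjusted p = 0.0211); fry does not compare a list with other genes, which differs by construction. The form of camera with an estimated correlation ended all 114 list calls, whereas with fry 2 of them fell below the threshold. In 69 further list tests only fry passed, and fry asks a different question from camera. At these depths 1.5-fold changes were recovered in 68.7 to 82.1% of simulated genes.

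The model that ignores day was also fitted to the 35 splits of the 8 libraries into 4 and 4. As many genes as with the systems (37, with 1674 at an unadjusted p under 0.05) were called by 2 splits, the real one included, so chance was not excluded for this model. The highest other split, by day, called 5382 genes and points to a structure of the samples, namely the day.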

Other observations

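The test of dividing cells in this part was chosen after the result was seen. The genes in this part were picked after their values were seen, and no list of them was tested. The cytokine receptor and STAT list did not pass over time (adjusted p = 0.946, adjusted p = 0.992 with an estimated correlation with 221-mIL21, adjusted p = 0.680, adjusted p = 0.847 with an estimated correlation with K562-mIL21). IL2RA, the high-affinity chain of the IL-2 receptor (GRCh38 chromosome 10, 6010689 to 6062367), fell from 305 ± 5.69 to 16.4 ± 0.721 CPM with 221-mIL21 (log2 fold change -4.22, SE 0.07, adjusted p = 3.7e-24) and from 92.1 ± 3.15 to 26.9 ± 0.533 CPM with K562-mIL21 (log2 fold change -1.78, SE 0.07, adjusted p = 1.3e-16). IRF4, a transcription factor of activated lymphocytes, fell 6.35-fold and 3.91-fold. The IL-18 receptor chain IL18RAP rose 3.74-fold and 2.35-fold, and the residency factor ZNF683 rose 66.6-fold and 3.17-fold.

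On day 14, these single genes differed between the systems. ITGA1, the collagen-binding integrin CD49a, had 7.15 ± 0.465 against 41.5 ± 1.44 CPM (log2 fold change -2.54, SE 0.10, adjusted p = 1.7e-15), and CXCR6, a receptor of liver-resident NK cells, 4.94 ± 0.715 against 20.04 ± 1.07 CPM (log2 fold change -2.02, SE 0.12, adjusted p = 3.2e-12). The transcription factors MAF and IKZF2 were 2.00-fold and 2.03-fold lower, whereas TOX2, a factor of NK cell maturation, was 2.35-fold higher. ZNF683 had 65.2 ± 7.75 against 41.5 ± 0.976 CPM, the other way from ITGA1 and CXCR6. The innate lymphoid list (adjusted p = 0.0523, adjusted p = 0.273 with an estimated correlation) and the homing receptor list (adjusted p = 0.266, adjusted p = 0.485 with an estimated correlation) did not pass.

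A larger share of dividing cells with 221-mIL21 might explain the higher MYC, ribosome and amino acid genes on day 7. After TMM scaling the genes of both cell cycle lists were not raised like these, with a median log2 fold change of -0.050 over 72 genes (SE across genes 0.0383). Of the 72, 16 were higher, 23 lower and 33 did not pass. The median of the MYC and ribosome biogenesis list was 0.24. With library size as the only scaling the median tested gene lay at 0.15, so the sign of the cell cycle median may depend on the scaling. The share of dividing cells is therefore not decided. Growth per cell, size and division rate were not measured.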
